A study of Mus musculus with 8 samples.

How the data were processed

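Messenger RNA with polyA tails was sequenced from Ly6Chi monocytes sorted from the livers of 8 male C57BL/6 mice, 8 weeks old, 24 h after 300 mg/kg acetaminophen was injected into the peritoneum of fasted animals. The livers were perfused and digested with collagenase before the sort. Each library came from 1 animal, started from 500 ng of RNA and was read as single reads on a NextSeq instrument. The 4 control mice carry floxed Commd10 alleles and are weight-matched littermates. The 4 deficient mice carry the same alleles and a Cre recombinase driven by the lysozyme M gene, Lyz2. No paired analysis was possible because the animal numbers are not shared between the groups.

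The authors deposited raw counts per gene, with 1 column per animal, and beside them a normalised signal. By its values, the normalised signal the authors deposited is each count divided by 1 factor per library. The submitters' processing notes list cutadapt, STAR 2.7.3a, HTSeq 0.12.4, DESeq2 1.26.0 and the GRCm38 genome, with no roles or order stated. Strandedness is not given, so counts of genes that overlap on opposite strands may mix. The count table has 15337 rows, which are 15336 genes and 1 cre transgene. Each row reaches at least 6 counts in some animal, so genes with lower counts are absent. Of the gene identifiers, 15324 are in the GENCODE M21 annotation, which gave positions on GRCm38, and 12 are not. The normalised signal was used only to compare the authors' factors with size factors computed here, whose ratio ranged from 1 to 1.00001.

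Total counts per animal ranged from 13327665 to 15759224, and trimmed mean of M-values (TMM) factors from 0.944 to 1.03. The 10 most abundant genes took 6.58% to 8.46% of the counts. A count of 0 was given an upper limit of 3 counts in that library, which covers counting error only, since reads without molecular identifiers are not independent molecules.

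Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the group, with a minimum count of 10 and a minimum total of 15, which left 12178 genes and removed 3158. Libraries were scaled by TMM, and the genotypes were compared with the edgeR quasi-likelihood F-test, two-sided, with Benjamini-Hochberg (BH) adjustment. A gene was called at an adjusted p under 0.05. Fold changes are log2 of deficient over control, with the standard error (SE) of the fit. CPM values use the same scaling, and log2 CPM a prior count of 2. Single values were compared by exact permutation tests, two-sided, whose smallest p is 0.0286 with 4 against 4 animals and 0.0556 when animals are exchanged only within a label set.

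The sample descriptions write the animal names in 2 ways, which part the mice into a lower-numbered set (controls 2 and 3, deficient 5 and 6) and a higher-numbered set (controls 10 and 11, deficient 12 and 13). These are called label sets here. The labels do not say what parts them, and in both sets the controls have the lower numbers. The test without a covariate, the model with the label set as a covariate, 39 gene lists and the rule for named genes were chosen before the data were examined. Applying the list tests and the gene rule to the model with the label set, and the alternatives run on that model, were chosen after the test without a covariate called 0 genes.

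The gene lists cover pathways, monocyte and macrophage states, other cell types of the liver, RNA quality and the neighbours of both modified loci. They hold 1066 genes, of which 995 are in the table. The 38 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, BH over the lists. Camera with an estimated correlation and fry (limma 3.58.1) were run beside it. Counts of called members are given over all genes tested and adjusted over the list alone. The rule for named genes took Commd10 and Lyz2, and in each direction the 8 called genes with the largest fold change. These needed a mean log2 CPM of at least 2 and no overlap between the groups, within each set where the label set was in the model. Unnamed gene models, pseudogenes and antigen receptor segments were left out of these. The rule further took up to 4 called members of each list by smallest p, or 2 as values where none was called, and the 5 called genes with the smallest p. With fewer than 10 called genes, the 10 with the smallest p are named as values.

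Alternatives were the DESeq2 1.42.0 Wald test, limma voom, relative log expression (RLE) factors, upper-quartile factors, no count filter, a filter of at least 5 CPM in 4 libraries, the label set, 1 surrogate variable (sva 3.50.0), other thresholds, and leaving out each animal. The code was tested on simulated data of the same size with 200 changed genes. Without a covariate it recovered 86% of genes changed 2-fold and 95% of those changed 4-fold with 0 false calls. With the label set it recovered 98% and 100% with 12 false calls, 5.71% of its calls. With no genotype effect planted it made 0 calls. The changed genes were picked at random, and each gene was drawn independently. In the real data the genotype and label-set fold changes were correlated, so these rates do not give the power or error there. All 8 animals were used.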

Results

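Gene expression was measured in Ly6Chi monocytes, the inflammatory monocytes that enter injured tissue, sorted from mouse livers 24 h after acetaminophen, in the necrotic and inflammatory phase of the injury. The groups were 4 control mice (replicates 2, 3, 10 and 11) and 4 mice that lack COMMD10 in myeloid cells (replicates 5, 6, 12 and 13), called deficient here. The comparison asks how monocytes with and without COMMD10 differ in their differentiation traits in the injured liver. The deficient mice alone carry the Cre, inserted in Lyz2, and no group carries the Cre with intact Commd10. Effects of COMMD10 loss, of the Cre and of the Lyz2 insertion therefore cannot be told apart. Total counts ranged from 13327665 to 15759224 per animal, with 15012 to 15161 genes detected. CPM values are means ± SD over the 4 animals of a group, and log2 fold changes are deficient over control with the SE of the fit.

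Commd10, the targeted gene (ENSMUSG00000042705, GRCm38 chromosome 18, 46958816 to 47234284), was lower in deficient monocytes. It stood at 27.3 ± 2.19 CPM (SD, n = 4) in controls and 14.2 ± 3.73 CPM (SD, n = 4) in deficient animals, a log2 fold change of -0.94 (SE 0.18). The 4 deficient animals lay at 8.74 to 17.0 CPM, all under the controls at 24.5 to 29.8 CPM (exact permutation test, p = 0.0286, the smallest that 4 against 4 animals can give). The log2 fold change was -0.74 in the lower-numbered label set and -1.21 in the higher-numbered set. The adjusted p was 0.0110 with the label set in the model and 0.290 without it (edgeR quasi-likelihood, BH). Counts cover the whole gene, so transcripts that lack the deleted part are not told apart from intact ones. The cre transgene had 122, 94, 37 and 77 counts in deficient replicates 5, 6, 12 and 13, and 0 in each control, which allows up to 0.225 CPM there.

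Lyz2, the lysozyme gene into which the Cre is inserted in this driver line (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), was at 12708 ± 3409 CPM (SD, n = 4) in controls and 4023 ± 3086 CPM (SD, n = 4) in deficient animals. Its level was 7333, 5597, 2847 and 315 CPM in deficient replicates 5, 6, 12 and 13. With the label set in the model Lyz2 fell by 1.95 on the log2 scale (SE 0.57, adjusted p = 0.0491, edgeR quasi-likelihood, BH), with -1.27 and -3.38 in the lower- and higher-numbered sets. That call was lost when any animal other than deficient replicate 13 was left out, and with the stricter count filter. Its neighbour and paralog Lyz1 (ENSMUSG00000069515, 117287797 to 117292868) rose from 34.5 ± 8.15 to 94.4 ± 38.4 CPM (SD, n = 4 each), a log2 fold change of 1.45 (SE 0.23, adjusted p = 0.00626, edgeR quasi-likelihood, BH). Reads of the paralogs can be hard to assign.

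**Figure D1:**
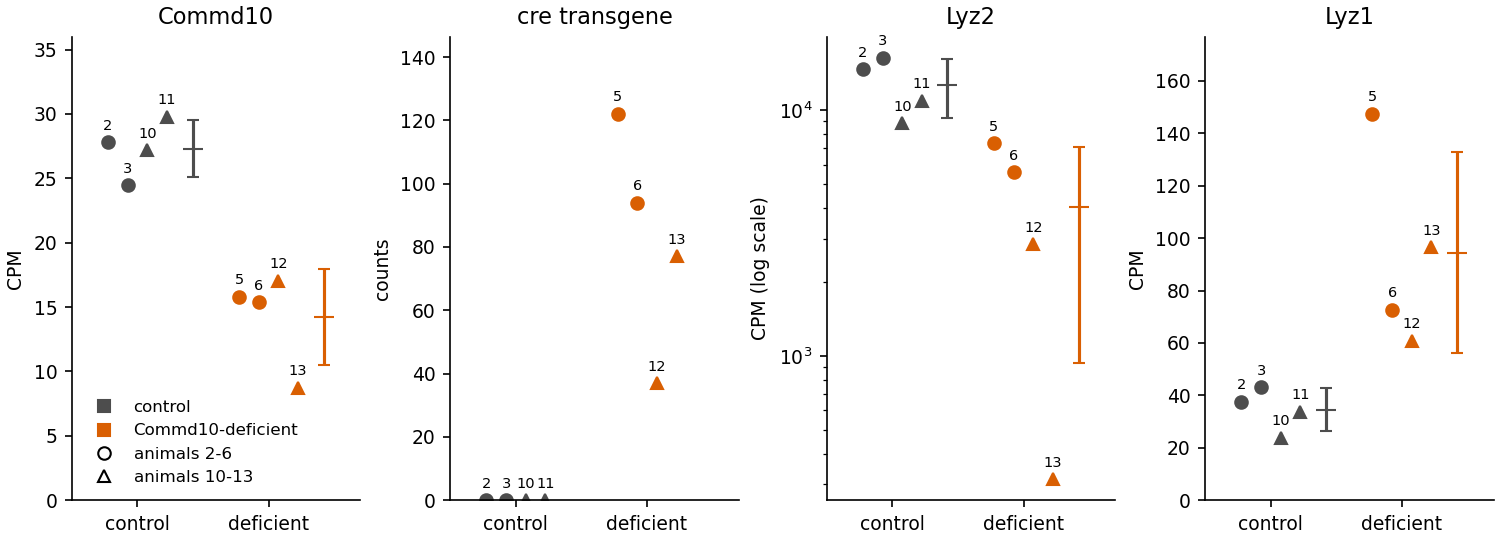
Each point is 1 animal, with the replicate number beside it, for Commd10, Lyz2 (log axis) and Lyz1 in CPM and for the cre transgene in counts; bars are the mean ± SD of 4 animals, and symbols mark the label sets. Commd10 lies at 24.5 to 29.8 CPM in controls and 8.74 to 17.0 CPM in deficient animals, and cre has counts in the deficient animals alone.

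The label sets separated the animals more than genotype did. The first principal component held 60.5% of the variance and parted the sets, and the second held 14.0% and ordered the genotypes within each set. In the higher-numbered set, 4496 genes differed from the lower-numbered set, 2263 higher and 2233 lower. The neutrophil-attracting chemokine gene Cxcl3 was higher there by 4.82 (log2, SE 0.13), the arginase gene Arg1 by 4.90 (SE 0.67), the cytokine gene Il6 by 4.48 (SE 0.33) and the lipid droplet gene Hilpda by 2.85 (SE 0.16). Cx3cr1, the fractalkine receptor of maturing monocytes, was lower there, at -1.45 (SE 0.20). Median correlations of log2 CPM between animals were 0.990 within a group and set, 0.983 between the genotypes of a set and 0.970 between the sets of a genotype.

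**Figure D2:**
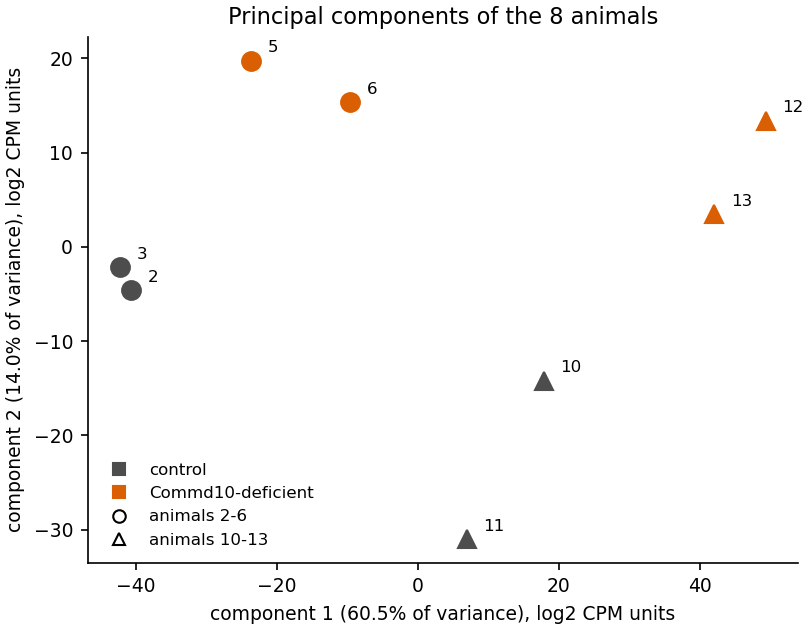
Each point is 1 animal on principal components 1 (60.5% of the variance) and 2 (14.0%) of log2 CPM, with its replicate number; colour is genotype and shape the label set. Animals of the lower-numbered set lie left of those of the higher-numbered set, and within each set the deficient animals lie to the right of and above the controls.

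Within the label sets, the cells sorted from deficient animals carried more message of genes such as Cxcl3, Arg1 and S100a8 and less of genes such as Ifit2 and Ifit3. With the label set in the model, 1697 of 12178 genes differed between the genotypes, 802 higher and 895 lower in deficient animals (edgeR quasi-likelihood, BH). With upper-quartile factors in place of TMM the balance was 641 higher and 1035 lower. Among called protein-coding genes with a mean log2 CPM of at least 2 and no overlap between the groups within either set, the largest rises were in Cxcl3 (log2 fold change 3.47, SE 0.12), Arg1 (3.12, SE 0.62), the alarmin gene S100a8 (3.10, SE 0.26), the platelet chemokine gene Ppbp (2.96, SE 0.31) and the adenylate kinase gene Ak4 (2.83, SE 0.27). The alarmin gene S100a9 (2.72, SE 0.33), the oxygen-sensing hydroxylase gene Egln3 (2.54, SE 0.42) and the endothelin receptor gene Ednrb (2.51, SE 0.28) followed. Beside Lyz2, the largest falls among the same genes were in the interferon-induced genes Ifit3b (-1.89, SE 0.22), Ifit3 (-1.71, SE 0.25), Ifit2 (-1.68, SE 0.24), Ifi213 (-1.55, SE 0.17) and Ifi206 (-1.48, SE 0.17), and in Olfml3 (-1.83, SE 0.27) and the surface sialomucin gene Cd34 (-1.55, SE 0.20). The 5 called genes with the smallest p were Cxcl3, Hilpda (2.01, SE 0.15), the sulfiredoxin gene Srxn1 (1.02, SE 0.08), S100a8 and the cytokine feedback gene Socs3 (0.69, SE 0.06).

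The test without a covariate called 0 genes (edgeR quasi-likelihood, lowest adjusted p = 0.273), while 1519 genes had an unadjusted p under 0.05 (700 higher, 819 lower, 609 expected by chance). On the same design DESeq2 called 145 genes, 134 of them among the 1697, and limma voom 0. The CPM of the groups did not overlap for 855 genes, 7.02% of those tested, where a random split of like animals gives 2.86% on average. Genes are not independent and the label sets differ, so whether this share exceeds chance was not tested. The 10 genes with the smallest p had the following log2 fold changes in that test. The cyclin gene Ccnb2 stood at 2.72 (SE 0.44), Wfdc21 at 2.53 (SE 0.41), the siderophore-binding lipocalin gene Lcn2 at 2.20 (SE 0.37), Serpinb1a at 0.93 and the phospholipase gene Plcb1 at 0.93. The chemokine gene Ccl5 stood at -0.99, Dpy19l3 at -1.03, the inflammasome sensor gene Nlrp1b at -0.49 and the lipid receptor gene Trem2 at -0.48. The neutrophil protease gene Prtn3, the remaining one, was at 5.20 ± 1.40 CPM in controls and 12.5 ± 2.43 CPM in deficient animals (SD, n = 4 each). All further values come from the model with the label set. In that model the number called fell to 697 without deficient replicate 12, 739 without control 11, 973 without control 2 and 1000 without deficient replicate 13, and was 46 in the lower-numbered and 646 in the higher-numbered set alone.

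Interferon-stimulated genes were lower in deficient monocytes as a group. Of 36 tested members of the type I interferon list, 34 fell and 0 rose (0 rose and 36 fell adjusted over the list alone). The antiviral sensor genes Oas3 (-1.05, SE 0.10) and Oasl2 (-1.18, SE 0.13) were among them, as were the tethering factor gene Bst2 (-0.75, SE 0.11) and Ifi27l2a (-0.76, SE 0.07). Oasl2 fell from 401 ± 117 to 189 ± 91.3 CPM (SD, n = 4 each), and its log2 fold change was -0.86 in the lower-numbered and -1.49 in the higher-numbered set. The list's camera test gave an adjusted p of 6.82e-41, with adjusted p = 0.224 with an estimated correlation. In the same animals summed hepatocyte markers were 433 ± 169 CPM in controls and 235 ± 25.5 CPM in deficient animals, and summed Kupffer cell markers 663 ± 132 and 472 ± 86.2 CPM (SD, n = 4 each). Exact permutation tests gave p = 0.0857 for each sum, and within the label sets 0.111 for hepatocyte and 0.0556, the smallest possible, for Kupffer cell markers, whose sum was lower in each deficient animal than in the controls of its set.

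Genes of antigen presentation on MHC class II were lower too. Of 19 tested, 9 fell and 1 rose (12 fell and 2 rose adjusted over the list alone). The invariant chain gene Cd74 fell from 3378 ± 526 to 1639 ± 529 CPM (SD, n = 4 each), a log2 fold change of -1.06 (SE 0.17), with -0.97 and -1.22 in the lower- and higher-numbered sets. The class II chain gene H2-Aa (-1.19, SE 0.20) and the peptide-loading genes H2-DMa (-0.78, SE 0.08) and H2-DMb1 (-0.87, SE 0.13) fell as well. The camera adjusted p was 1.25e-06, with adjusted p = 0.224 with an estimated correlation. Among dendritic cell markers, which include class II-rich cells, 4 of 19 fell and 0 rose (6 and 0 adjusted over the list alone), among them the growth factor receptor gene Flt3 (-1.19, SE 0.22). That list had an adjusted p of 0.00487 by camera, with adjusted p = 0.347 with an estimated correlation, and summed dendritic cell markers were 679 ± 51.6 CPM in controls and 620 ± 63.3 CPM in deficient animals (SD, n = 4 each).

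Genes of glycolysis and the hypoxia response were higher in deficient monocytes. Of 33 tested, 25 rose and 0 fell (26 rose and 1 fell adjusted over the list alone). The triosephosphate isomerase gene Tpi1 rose from 300.3 ± 74.9 to 610.1 ± 267 CPM (SD, n = 4 each), a log2 fold change of 0.95 (SE 0.11), with 0.69 and 1.20 in the lower- and higher-numbered sets. The glycolytic gene Pgam1 (0.84, SE 0.10), the pyruvate dehydrogenase kinase gene Pdk1 (0.84, SE 0.09) and the hypoxia-induced gene Ankrd37 (1.45, SE 0.17) rose too. The camera adjusted p was 2.69e-24, with adjusted p = 0.258 with an estimated correlation. In the NRF2 antioxidant list 9 of 23 rose and 1 fell (11 and 1 adjusted over the list alone), with the glutathione reductase gene Gsr (0.47, SE 0.09), the thioredoxin gene Txn1 (0.39, SE 0.05) and the efflux pump gene Abcc1 (0.47, SE 0.07) beside Srxn1. By camera it had an adjusted p of 2.54e-06, with adjusted p = 0.258 with an estimated correlation. In the same animals summed neutrophil markers were 726 ± 104 CPM in controls and 1001 ± 89.8 CPM in deficient animals, and summed hepatocyte markers 433 ± 169 and 235 ± 25.5 CPM (SD, n = 4 each).

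Neutrophil granule and alarmin genes were higher in the cells sorted from deficient animals. Neutrophils among the sorted cells stay open as the source of S100a8 and S100a9. Of 14 tested neutrophil markers, 8 rose and 0 fell (10 and 0 adjusted over the list alone). Lcn2 rose from 34.1 ± 13.1 to 156 ± 59.3 CPM (SD, n = 4 each), a log2 fold change of 2.15 (SE 0.24), with 2.04 and 2.36 in the lower- and higher-numbered sets. S100a8 rose from 11.2 ± 7.52 to 92.1 ± 48.2 CPM (SD, n = 4 each), with log2 fold changes of 3.35 and 2.93 in the sets, and Wfdc21 by 2.55 (SE 0.22) and Prtn3 by 1.27 (SE 0.16) on the log2 scale. By camera this list had an adjusted p of 9.06e-14, with adjusted p = 0.0672 with an estimated correlation. Summed neutrophil markers were 726 ± 104 CPM in controls and 1001 ± 89.8 CPM in deficient animals (SD, n = 4 each, exact permutation test, p = 0.0286, adjusted p = 0.343 over 12 marker sums). That p is the smallest 4 against 4 animals can give, and a single sum at it cannot pass adjustment over 12.

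Matrix-remodelling genes rose in the same animals. Of 22 tested, 11 rose and 2 fell (13 and 2 adjusted over the list alone). The collagenase gene Mmp8, which the neutrophil list also holds, rose from 110 ± 30.7 to 207 ± 33.3 CPM (SD, n = 4 each), a log2 fold change of 0.91 (SE 0.13). The protease genes Adam8 (1.09, SE 0.12), Mmp19 (1.06, SE 0.12) and Mmp12 (1.31, SE 0.23) rose, with 1.03 and 1.17 for Adam8 in the lower- and higher-numbered sets. The list's adjusted p by camera was 6.86e-07, with adjusted p = 0.0672 with an estimated correlation.

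Some inflammatory and repair genes were also higher. Of 23 inflammatory cytokine and chemokine genes, 7 rose and 1 fell (12 and 3 adjusted over the list alone). The monocyte-attracting chemokine gene Ccl2 (1.15, SE 0.22) and Il6 (1.76, SE 0.30) rose beside Cxcl3, and the T cell-attracting chemokine gene Ccl5 fell from 5.04 ± 0.308 to 2.53 ± 0.484 CPM (SD, n = 4 each). This list had a camera adjusted p of 3.43e-06, with adjusted p = 0.258 with an estimated correlation. Of 27 repair and alternative activation genes, 7 rose and 1 fell (10 and 1 adjusted over the list alone). Arg1 stood at 766 ± 1015 CPM in controls and 4436 ± 4815 CPM in deficient animals (SD, n = 4 each), with log2 fold changes of 3.10 and 2.63 in the lower- and higher-numbered sets. The vascular growth factor gene Vegfa (1.52, SE 0.31) and the protease inhibitor gene Slpi (0.72, SE 0.13) rose with it. That list's camera adjusted p was 3.00e-04, with adjusted p = 0.224 with an estimated correlation. The NF-kB feedback list, with 4 of 25 higher and 0 lower (4 and 0 adjusted over the list alone), did not pass (adjusted p = 0.0557, camera). Summed neutrophil markers, given above, were higher in each deficient animal than in each control.

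More markers of monocyte maturation fell than rose in deficient monocytes, and identity markers moved both ways. In the monocyte-to-macrophage maturation list 9 of 26 fell and 4 rose (12 fell and 5 rose adjusted over the list alone). The selenoprotein P gene Selenop fell by 0.70 (log2, SE 0.12), while the tetraspanin gene Cd9 rose by 0.70 (SE 0.12). The camera adjusted p was 0.0211, with adjusted p = 0.554 with an estimated correlation, and 0.0520 without control 11 and 0.0854 without control 2. In the Ly6Clo monocyte list 4 of 17 fell and 1 rose (8 and 1 adjusted over the list alone). Cx3cr1 fell from 771 ± 340 to 361 ± 233 CPM (SD, n = 4 each), a log2 fold change of -1.24 (SE 0.20), with -0.92 and -1.58 in the lower- and higher-numbered sets, and the integrin gene Itgal fell (-0.70, SE 0.13). That list had a camera adjusted p of 8.26e-04, with adjusted p = 0.365 with an estimated correlation. The Ly6Chi monocyte identity list had 5 of 19 higher and 4 lower (8 and 6 adjusted over the list alone) and did not pass (adjusted p = 0.682, camera). In it, the integrin gene Itgam (0.62, SE 0.12) rose, and the stem cell antigen gene Ly6a (-1.32, SE 0.13), Plac8 (-0.55, SE 0.07) and Ms4a4c (-0.61, SE 0.09) fell.

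More lipid-associated macrophage genes rose than fell. Of 20 tested, 7 rose and 2 fell (10 and 2 adjusted over the list alone). The fatty acid receptor gene Cd36 (1.22, SE 0.13) and the lipid droplet gene Plin2 (0.83, SE 0.07) rose, and Trem2 fell from 284 ± 24.5 to 204 ± 7.66 CPM (SD, n = 4 each), a log2 fold change of -0.48 (SE 0.07), with -0.50 and -0.45 in the lower- and higher-numbered sets. The list was higher by camera, at an adjusted p of 3.00e-04, with adjusted p = 0.365 with an estimated correlation. Kupffer cell markers, which resident macrophages carry, had 4 of 12 lower and 0 higher (5 lower and 1 higher adjusted over the list alone), with the prostaglandin dehydrogenase gene Hpgd at -1.25 (SE 0.13). Their camera adjusted p was 0.00788, with adjusted p = 0.365 with an estimated correlation.

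**Figure D3:**
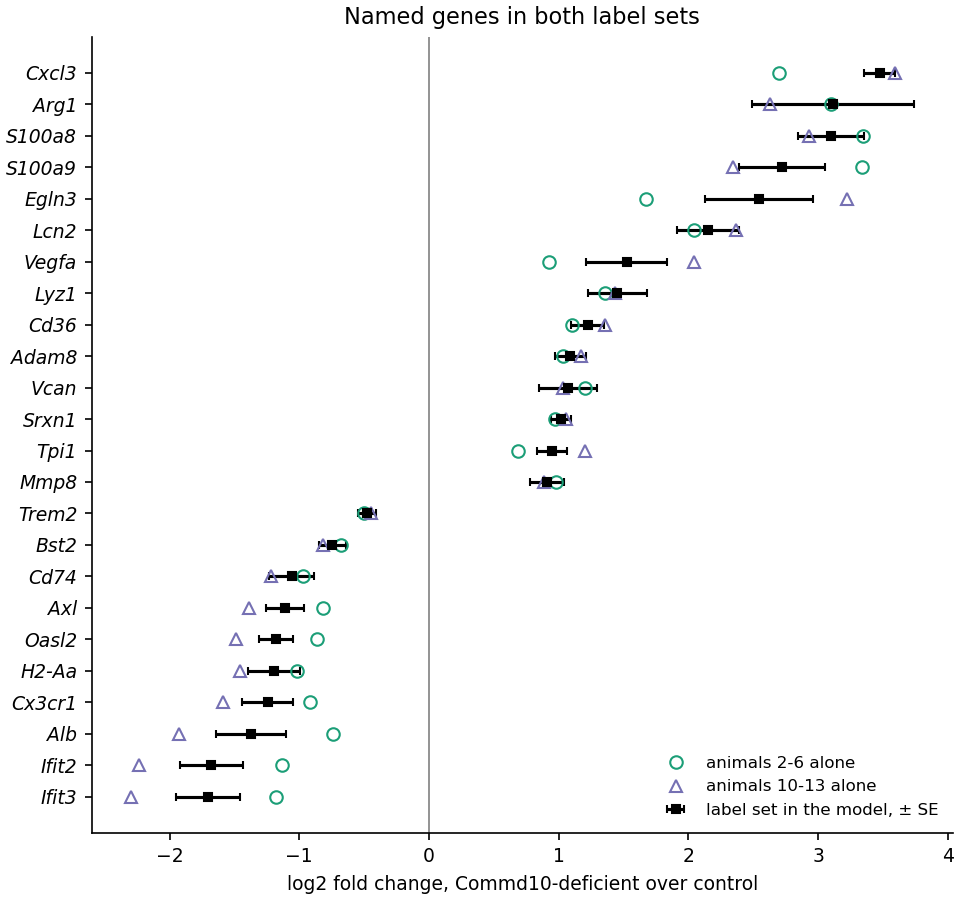
Log2 fold changes of named genes, deficient over control. Squares are fits with the label set in the model (bars are ± SE). Circles and triangles are differences of mean log2 CPM within each set of 2 against 2 animals. Each gene has the same sign in both sets, from 3.47 for Cxcl3 to -1.71 for Ifit3. The genes were picked from those called over both sets, a choice that favours a shared sign.

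Hepatocyte marker transcripts were lower in deficient samples, mainly in the higher-numbered set. Their sum there was 488 and 631 CPM in controls 10 and 11 and 230 and 252 CPM in deficient replicates 12 and 13. In the lower-numbered set the groups overlapped, with control 2 at 232 CPM and deficient replicate 5 at 259 CPM. The exact permutation test within the sets gave p = 0.111 for this sum. Of 27 hepatocyte markers 10 fell and 0 rose (16 and 0 adjusted over the list alone), and the albumin gene Alb fell from 139 ± 55.6 to 51.8 ± 9.24 CPM (SD, n = 4 each), a log2 fold change of -1.37 (SE 0.27), with -0.74 and -1.93 in the lower- and higher-numbered sets. The hepatocyte list had a camera adjusted p of 6.01e-07, with adjusted p = 0.382 with an estimated correlation. Of 17 sinusoidal endothelial markers 2 fell and 0 rose (2 and 0 adjusted over the list alone), Clec4g and Eng, and the calls of both were lost in at least 1 alternative. Summed endothelial markers were 131 ± 104 CPM in controls, with control 11 at 286 CPM, and 70.6 ± 30.0 CPM in deficient animals (SD, n = 4 each, exact permutation test, p = 0.257). That list had a camera adjusted p of 9.11e-04, with adjusted p = 0.554 with an estimated correlation. In the B and plasma cell list the immunoglobulin gene Ighm (-0.93, SE 0.08) and the receptor chain gene Cd79b (-0.94, SE 0.11) fell and the J chain gene Jchain rose (2.41, SE 0.48). It had 3 of 14 lower and 2 higher (5 and 2 adjusted over the list alone) and a camera adjusted p of 0.00591, with adjusted p = 0.365 with an estimated correlation.

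Lists of T and NK cells (1 of 15 higher, 2 lower; 1 and 2 adjusted over the list alone; adjusted p = 0.444), stellate cells and fibroblasts (0 of 6 either way, also adjusted over the list alone; adjusted p = 0.641) and erythroid cells and platelets (1 of 7 higher, Ppbp, also adjusted over the list alone; adjusted p = 0.0778) did not pass by camera. Summed T and NK cell markers were 52.0 ± 26.6 CPM in controls and 67.0 ± 37.2 CPM in deficient animals (SD, n = 4 each), higher in each deficient animal than in the controls of its set (exact permutation test within the sets, p = 0.0556, the smallest possible; p = 0.514 without the sets), while their mean log2 CPM differed by -0.12. Only 4 eosinophil, basophil and mast cell markers were tested, 0 of them called, so that list had no test. Immediate early and dissociation genes, which mark the handling of cells, had 1 of 29 higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.786, camera). Without deficient replicate 5 the Dissociation and immediate early list with the label set was higher in deficient animals (adjusted p = 0.0233, camera), and without control 10 or deficient replicate 6 the direction was reversed without a call. Mitochondrially encoded genes had 0 of 7 called (also 0 adjusted over the list alone; adjusted p = 0.884, camera).

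**Figure D4:**
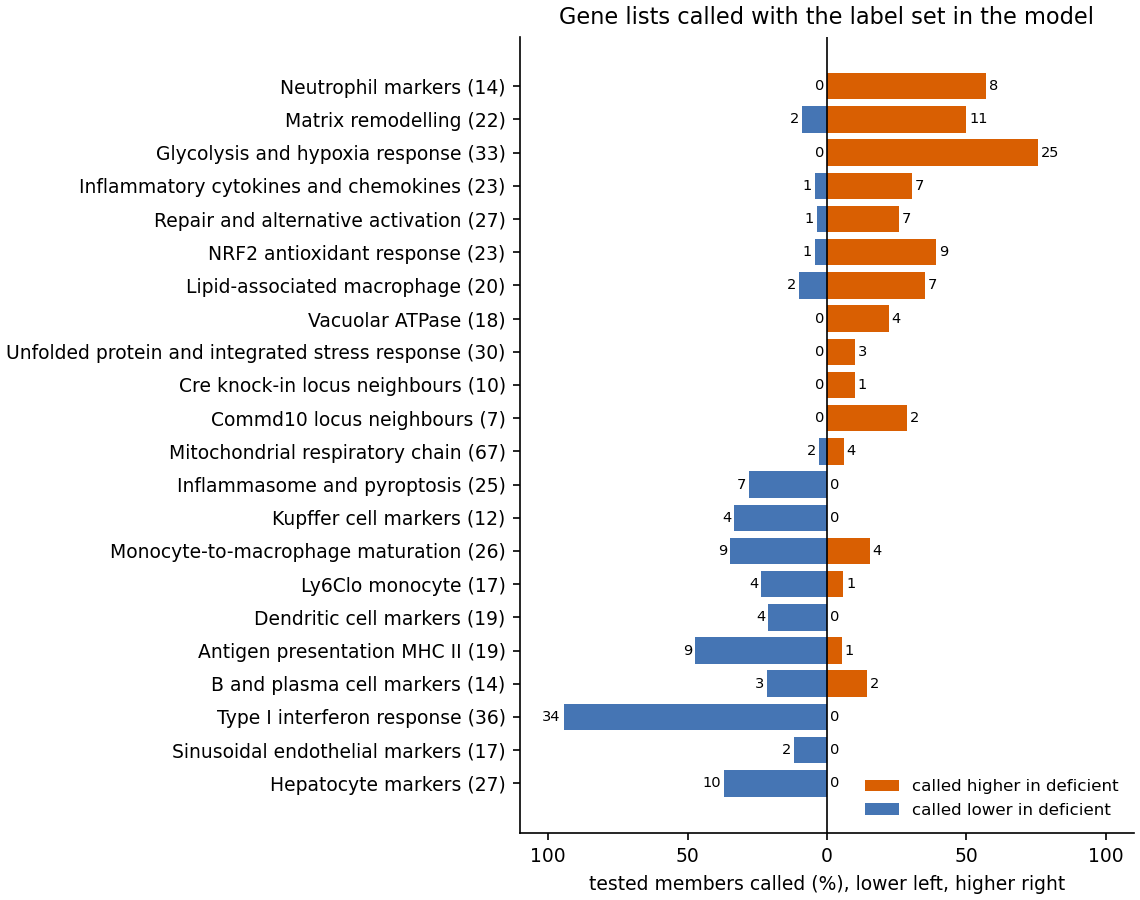
Share of tested members called higher (right) and lower (left) in cells sorted from deficient animals, in percent, for the 22 lists that passed by camera with the label set in the model. Numbers at the bars count called members and numbers in brackets tested members. The interferon list has 34 of 36 lower, and the glycolysis and hypoxia list 25 of 33 higher.

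The COMMD-CCC complex list, the trafficking complex to which COMMD proteins belong, had 1 of 18 higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p = 0.682, camera). The called member was the retromer gene Vps29 (0.23, SE 0.07), whose call was lost in 11 of 14 alternatives. Among neighbours of Commd10, 2 of 7 rose and 0 fell (3 and 0 adjusted over the list alone), with Ap3s1, a trafficking adaptor gene, at 0.44 (SE 0.08) and the initiation factor gene Eif1a at 0.45 (SE 0.09), whose call was lost without deficient replicate 12. Their camera adjusted p was 0.0395, with adjusted p = 0.279 with an estimated correlation, and 0.0509 to 0.0795 without control 10, control 3 or deficient replicate 6. Among neighbours of the Cre insertion 1 of 10 rose and 0 fell, which was Lyz1 (3 and 0 adjusted over the list alone). Their camera adjusted p was 0.00780, with adjusted p = 0.365 with an estimated correlation.

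The vacuolar ATPase list, the proton pump of acidic organelles, had 4 of 18 higher and 0 lower (7 and 0 adjusted over the list alone), with Atp6v1a at 0.45 (SE 0.07) and Atp6v1d at 0.32 (SE 0.05). Its camera adjusted p was 4.53e-04, with adjusted p = 0.365 with an estimated correlation. The unfolded protein and integrated stress response list had 3 of 30 higher and 0 lower (1 and 0 adjusted over the list alone), with the transcription factor gene Atf5 at 0.85 (SE 0.13). Its camera adjusted p was 9.35e-04, with adjusted p = 0.365 with an estimated correlation. The inflammasome and pyroptosis list had 0 of 25 higher and 7 lower (0 and 10 adjusted over the list alone), with Nlrp1b at -0.49 (SE 0.07). Its camera adjusted p was 0.00384, with adjusted p = 0.365 with an estimated correlation. The mitochondrial respiratory chain list had 4 of 67 higher and 2 lower (2 and 0 adjusted over the list alone), with the cytochrome oxidase gene Cox6c at 0.31 (SE 0.05). Neither count was a larger share than among all 12178 tested genes (802 higher, 895 lower). The list's median log2 fold change was 0.066. Its camera adjusted p was 0.0385, with adjusted p = 0.766 with an estimated correlation, and 0.118 to 0.161 without control 11, control 3, deficient replicate 6 or deficient replicate 12. The cell cycle list had 2 of 34 higher and 1 lower (2 and 1 adjusted over the list alone), with Ccnb2 at 2.67 (SE 0.34), and did not pass (adjusted p = 0.139, camera). Ribosomal protein genes (1 of 75 higher, 0 and 0 adjusted over the list alone, adjusted p = 0.682) and cholesterol synthesis genes (1 of 24 lower, 0 and 1 adjusted over the list alone, adjusted p = 0.682) did not pass by camera.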

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

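The tests of explanations in this part were chosen only after the result was seen, except the splits of the animals and the test of drift with animal number. Without a covariate the true grouping called 0 genes, so all 35 splits of the 8 animals into 4 and 4 gave at least as many by construction, and the count of splits decides nothing about chance. The highest other split, the label sets themselves, called 2708 genes, which points to a structure of the samples. With the label set in the model the true grouping called 1697 genes and the highest other split within the sets called 0 (1 of 18 splits gave as many, too few splits for a share under 0.05).

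Across genes, which are not independent replicates, the genotype and label-set fold changes were correlated (r = 0.52, rho = 0.57, slope 0.46 over 8524 genes). Simulated data with no genotype effect gave a correlation of -0.005, but each gene was drawn independently there. The simulation therefore cannot show how large a correlation the chance placement of animals along a shared axis gives. Of the 1697 called genes 1255 also differed between the sets, 10 of them with the opposite sign. If deficient animals only lay further along the axis between the sets, as with longer handling, the 17 immediate early genes higher in the higher-numbered set would differ by a median of 0.65 between the genotypes, but their median was -0.038 (SD 0.31), which argues against handling time as the whole cause. With each animal left out in turn, the observed median was -0.18 to 0.05 where 0.52 to 0.71 was expected, and without deficient replicate 5, where the whole list was called higher, it was 0.03 against 0.69. Drift with animal number cannot be told apart from genotype, since controls have the lower numbers in both sets. For 1 step of number, drift needs a slope of 0.449 in the higher-numbered and 0.181 in the lower-numbered set. In the higher-numbered set the slopes ran opposite to drift, at -0.35 for controls and -0.21 for deficient animals. In the lower-numbered set they were 0.04 and 0.16, the larger being 0.904 of what drift needs. A difference between the genotypes in the livers' injury, or in the monocytes themselves, stays open and was not tested.

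The higher neutrophil marker transcripts could come from neutrophils in the sorted cells or from the monocytes. Neutrophils carry S100a8 and S100a9 as their most abundant transcripts, but these gained only 0.530 times as much CPM as Lcn2 and Mmp8 in the higher-numbered set (144 against 271 CPM) and less in the other (56.6 against 166 CPM), which argues against neutrophils as the source of the Lcn2 and Mmp8 gain. For S100a8 and S100a9 they stay open: Cxcr2, a neutrophil receptor gene, had a log2 fold change of 0.95 that was not called (adjusted p = 0.0665, edgeR quasi-likelihood, BH), while Csf3r, whose high level here could hide a small share, had a change of -78.5 and -12.5 CPM in the higher- and lower-numbered sets and was not called either. Younger monocytes close to the dividing precursor cannot be told apart either: of 16 listed precursor genes 9 were tested, 2 rose (Mki67 and Pclaf), and Flt3 fell. The gate for Ly6Chi monocytes would be meant to remove neutrophils.

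The low Lyz2 could reflect reads moved to its paralog Lyz1, but the gain of Lyz1, 59.8 CPM, was 0.689% of the 8685 CPM lost from Lyz2, which argues against it for Lyz2. For the high Lyz1, a fixed share of Lyz2 reads assigned to Lyz1 would have fallen with Lyz2. Lyz1 instead rose, from 23.7 to 43.0 CPM in controls to 60.8 to 147 CPM in deficient animals. These values argue against a fixed share as the source. A share that differs between the genotypes stays open, since 0.689% of the lost reads would supply the whole gain. The order within the sets differed. Deficient replicate 6 had less Lyz2 than replicate 5 (5597 against 7333 CPM) and also less Lyz1 (72.6 against 147 CPM). Replicate 13 had less Lyz2 than replicate 12 (315 against 2847 CPM) and more Lyz1 (96.6 against 60.8 CPM). The very low Lyz2 of deficient replicate 13 could reflect a second Cre copy, with both Lyz2 alleles disrupted. Its cre level was 0.596 times the highest of the other deficient animals and above the lowest, which leaves this open. That comparison crosses the label sets. Against replicate 12, the other deficient animal of its set, it had more cre (77 against 37 counts) and less Lyz2 (315 against 2847 CPM). It also had less Commd10 (8.74 against 17.0 CPM). These differences go with a second copy but rest on 1 pair of animals.

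Cre transgene counts, outside the gene comparison, were 122, 94, 37 and 77 in deficient replicates 5, 6, 12 and 13 against 0 in the controls. Cxcl9, an interferon-induced chemokine gene, had a genotype difference that differed between the sets by -2.24 (log2, adjusted p = 0.0117, edgeR quasi-likelihood interaction, BH; -0.29 in the lower- and -2.52 in the higher-numbered set). Nlrc5, a regulator gene of MHC class I, differed between the sets by -0.94 (-0.15 and -1.08), and the chemokine gene Ccl6 by 1.12 (-0.06 and 1.07), each at an adjusted p of 0.0433 (edgeR quasi-likelihood, BH). G530011O06Rik differed by 8.30 (lower in deficient animals of the lower-numbered set, 3.45 in the higher-numbered set) and Mid1 by 4.69 (-1.51 and 2.75) at the same adjusted p of 0.0433 (edgeR quasi-likelihood, BH). These 5 genes were named after their values were seen.

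In 5 of 280 groups of 4 animals, 1 animal stood far from the rest. About 14 would be expected if the groups were independent and each held 4 like animals. Here each group mixes animals of both label sets, which differ strongly, and the groups share the same animals. The count therefore cannot show whether there were more or fewer such animals than chance gives. Deficient replicate 6 had 34.5 CPM of Plcb1 against 50.2 to 52.1 in the others, a gap of 0.893 of the range. Control 11 had 16.9 CPM of Clec4g against 1.90 to 4.06 (0.857 of the range), 47.9 CPM of Eng against 26.1 to 28.5 (0.892) and a summed 286 CPM of sinusoidal endothelial markers against 73.4 to 90.1 (0.922). Control 2 had a summed 17457 CPM of mitochondrially encoded genes against 19030 to 19260 (0.872).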

How the results depend on the processing

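All alternatives to the model with the label set were chosen after the data were seen; those without a covariate were planned. Without a covariate, the number of genes called was 0 with limma voom, RLE or upper-quartile factors, no filter, the stricter filter, an adjusted p under 0.1 and each animal left out. It was 145 with DESeq2 (79 higher, 66 lower), 141 with 1 surrogate variable (65 and 76) and 1697 with the label set (802 and 895). Commd10 passed at -0.94 with DESeq2, -0.94 with the label set and -0.92 with 1 surrogate variable. With the label set in the model DESeq2 called 1836 genes, 1562 of them shared, and limma voom 1695, 1649 shared. At an adjusted p under 0.1 the number of genes called with the label set was 2718, the number of genes called higher with the label set 1305 and the number of genes called lower with the label set 1413. Other counts were 249 with an absolute log2 fold change of at least 1 (131 and 118), 646 in the higher-numbered set alone (280 and 366) and 46 in the lower-numbered set alone (31 and 15). Leaving out 1 animal gave 697 to 1685 genes (323 to 824 higher, 374 to 861 lower): 697 without deficient replicate 12, 739 without control 11, 973 without control 2 and 1000 without deficient replicate 13, and without control 3 506 higher. Of 128 named genes called, 88 kept the call in each alternative fit that tested them and 40 lost it in at least 1. The losses were most without deficient replicate 12 (36) and control 11 (31). The stricter filter left some of these genes untested (107 kept, 3 lost). The other thresholds and the fits of each label set alone are not part of this count. Upper-quartile factors moved the median log2 fold change of all genes to -0.03 and the calls to 641 higher and 1035 lower. Gene lists called were 19 without and 22 with the label set, 0 and 0 with an estimated correlation, and 3 and 13 with fry; leaving out 1 animal gave 16 to 21 and 19 to 24. Values that changed sign were not called: with 1 surrogate variable Fabp4 was -0.14, Ier3 -0.012 and Zc3h12a -0.10. Lists that changed direction are given with their adjusted p. With the stricter filter these were the Cell cycle list (0.465, called without that filter), the Cytosolic ribosome list (0.868) and the Mitochondrially encoded list (0.978), and the Chemokine receptors and adhesion list changed with fry (0.984) and the label set (0.853). Some lists changed direction with 1 or more animals left out, and the adjusted p over all animals left out in turn follows. Without a covariate it was 0.0236 to 0.939 for the Inflammatory cytokines and chemokines list, 0.220 to 0.912 for the Cholesterol synthesis and uptake list, 0.769 to 0.985 for the Chemokine receptors and adhesion list, 0.287 to 0.985 for the Toll-like receptor signalling list, 0.243 to 0.940 for the Cytosolic ribosome list, 0.0751 to 0.847 for the Dissociation and immediate early list and 0.687 to 0.961 for the Mitochondrially encoded list. In the other model it was 0.236 to 0.948 for the Lysosome and phagosome maturation list with the label set, 0.656 to 0.963 for the Efferocytosis and scavenger receptors list with the label set, 0.195 to 0.987 for the Cholesterol synthesis and uptake list with the label set, 0.632 to 0.963 for the Chemokine receptors and adhesion list with the label set, 0.414 to 0.846 for the Cytosolic ribosome list with the label set, 0.0233 to 0.987 for the Dissociation and immediate early list with the label set and 0.667 to 0.963 for the Mitochondrially encoded list with the label set. As mean log2 CPM the Dissociation and immediate early marker sum differed by 0.018 and the T and NK cell markers marker sum by -0.12, against -0.05 and 0.34 as sums. The cause of these changes was not tested. At 13327665 to 15759224 counts per animal, 3158 genes were too low to test.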

Other observations

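In this part the list tests with the label set in the model were chosen only after the result without it was seen, and the test of the marker sum was planned. The Toll-like receptor list, with 2 of 31 higher and 4 lower (4 and 7 adjusted over the list alone), did not pass (adjusted p = 0.485, camera), and its median of 0.01 and mean of -0.06 differed in sign. Among its called members, the receptor gene Tlr9 fell by 0.75 on the log2 scale (SE 0.09), with -0.59 and -0.92 in the lower- and higher-numbered sets. Tlr3, a receptor gene for double-stranded RNA (-1.15, SE 0.22), and Unc93b1, whose product carries such receptors to endosomes (-0.47, SE 0.07), fell too.

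Lists of phagocytic cargo handling moved both ways. In the efferocytosis and scavenger receptor list 5 of 28 rose and 6 fell (6 and 7 adjusted over the list alone; adjusted p = 0.940, camera). The receptor kinase gene Axl fell from 740 ± 230 to 364 ± 171 CPM (SD, n = 4 each), a log2 fold change of -1.11 (SE 0.15). Its bridging ligand gene Gas6 fell by 1.31 (SE 0.35). For Gas6 the groups overlapped in the lower-numbered set, with control 3 at 11.0 CPM and deficient replicate 5 at 11.9 CPM. The oxidised lipoprotein receptor gene Olr1 rose by 1.09 (SE 0.15) and the annexin gene Anxa1 by 0.46 (SE 0.09). In the lysosome and phagosome maturation list 5 of 46 rose and 6 fell (7 and 7 adjusted over the list alone; adjusted p = 0.682, camera), and its median of -0.07 and mean of 0.01 differed in sign. The cathepsin genes Ctsl (1.08, SE 0.20) and Ctsh (-0.35, SE 0.06) went opposite ways. In the LXR and cholesterol efflux list 3 of 18 rose and 1 fell (3 and 2 adjusted over the list alone; adjusted p = 0.683, camera), with the apolipoprotein gene Apoe at -0.73 (SE 0.18), a call lost without at least 1 animal. In the chemokine receptor and adhesion list 3 of 27 rose and 6 fell (8 and 7 adjusted over the list alone; adjusted p = 0.853, camera), with Cxcr3 at -1.21 (SE 0.29) and the selectin ligand gene Selplg at -0.46 (SE 0.06). Its median of 0.09 and mean of -0.03 differed in sign, as did those of the immediate early and dissociation list (-0.02 and 0.02).

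Summed immediate early and dissociation genes differed more between the label sets than between the genotypes. They were 10467 to 14895 CPM in the lower-numbered and 23322 to 30715 CPM in the higher-numbered set, and 19989 ± 9474 CPM in controls and 18885 ± 7527 CPM in deficient animals (SD, n = 4 each, exact permutation test, p = 0.914). The Dissociation and immediate early list with the label set was higher in deficient animals without deficient replicate 5 (adjusted p = 0.0233, camera).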
